A study of Mus musculus with 2 samples.

How the data were processed

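The series measured histone H3 monomethylated at lysine 4 (H3K4me1), a mark found around enhancers and beside active promoters, by chromatin immunoprecipitation and sequencing of mouse embryonic heart. Per the labels, the hearts came from pooled male and female embryos at day 14.5, and library fragments were selected at 300 to 500 bp. There was 1 group of 2 biological replicates. Per the labels, replicate 1 joined 3 technical replicates and replicate 2 had 1. Per the labels, each replicate came from its own tissue sample of pooled embryos; the numbers of embryos are not given in the sources used here.

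The authors deposited 4 peak lists in coordinates of the mouse build mm10, per the file descriptions deposited with each sample. Each replicate had its own list. A pooled list was called on both replicates together, and a list named replicated was derived from the pooled list and the replicates' lists. The aligner, the peak caller and its threshold are not given in the sources used here. Each peak carries a signal value that the authors' peak caller wrote, taken here as enrichment over the control on the scale of that list. The file descriptions name 2 further files for replicate 1 and 1 for replicate 2, which were taken as controls. Each also carries the −log10 of a p-value and of a q-value, likewise deposited by the authors. These values belong to the peak and were used only to describe, rank or filter peaks within a list, except that the replicates' values were correlated over matched peaks. The lowest −log10 p was between 2.01 and 2.05 in the 4 lists. Read counts were not part of the peak lists, so sequencing depth is unknown and no interval that needs it was computed. Intervals on shares of peaks and of matches are exact binomial intervals at the 95% level, the interval on X-linked genes is a Wilson interval, and all of them cover counting error only.

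Positions were set against the GRCm38.p6 genome sequence, the assembly that mm10 names, and the GENCODE M21 basic annotation. No peak ran past the end of a reference chromosome. Peaks outside the autosomes, X and Y were left out, which removed 1 peak from each replicate's list and 1 from the pooled list. Coordinates are given 1-based. A gene's start site was that of its transcript with the best APPRIS principal rank, the longest of those tied, or the longest transcript where none was principal. All 250 genes of the lists were matched by symbol.

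The tests, lists and settings of this paragraph and the next were fixed before the data were examined, except where said otherwise. A peak counted as shared when it overlapped a peak of the other list by at least 50% of the length of either. Observed overlaps and annotations were set beside 100 random placements of the same peak lengths (for overlaps, those of replicate 2) on the same chromosome outside assembly gaps. Signal values were correlated across peaks matched by largest overlap, and regions are not independent replicates. Peak midpoints were assigned to promoters (within 1 kb of a start site), then 5' UTR or coding exons, 3' UTRs, noncoding exons, introns and intergenic sequence. Profiles around start sites used autosomal protein coding genes, divided at an observed to expected CpG ratio of 0.6 in the 1 kb around the start site.

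For genes, the value was the percent of the 100 kb centred on the start site that peaks covered. The median of each list was compared with 10000 random lists of protein coding genes, matched by quintiles of the number of start sites in the window and of its GC content. Random lists were drawn gene by gene with replacement within these classes, so this test, called a permutation test in the report, permutes list membership in all but the replacement. Its two-sided empirical p was adjusted by Benjamini-Hochberg over 15 lists. Neither gene length nor the CpG ratio at the start site was matched. Windows of genes on the same list or on different lists can overlap. The random draws did not reproduce neighbouring members, so p can be too small for lists that hold them. The lists were cardiac transcription factors, cardiomyocyte contractile genes, cardiac calcium handling and conduction genes, cardiac signalling, endothelium and endocardium, epicardium, cushion and fibroblast, smooth muscle and pericyte, erythroid, immune, neural, liver, skeletal muscle, endoderm epithelium and housekeeping. Broad domains were peaks joined when under 3 kb apart. The genes nearest to the top 1% of domains by covered length were tested for each list by Fisher's exact test against all protein coding genes nearest to any domain.

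Matches to 18 consensus motifs were counted on both strands in distal peaks, whose midpoints lay over 2.5 kb from any start site. They were set beside regions of the same length and chromosome, with GC content within 2 percentage points, that held no pooled peak. Valleys were gaps of 150 to 1000 bp between neighbouring distal peaks, set beside the peaks on both sides. The test over autosomes had been planned as a sign or permutation test. The direction of the difference on each of 19 autosomes entered an exact two-sided sign test, leaving out ties, with Benjamini-Hochberg adjustment over the motifs. The log2 ratio was averaged over autosomes with matches in both sets. The first version of this test used only those autosomes and did not leave out ties. It was replaced after its output had been seen, because autosomes without a match in 1 set carry information on direction. Of the calls in distal peaks and valleys in the main setting, this changed that of RFX alone. Autosomes are not biological replicates. Lists and motifs were called at an adjusted p under 0.05.

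Genes named in the text were fixed by rule: the 20 genes with the highest covered percent whose windows do not overlap a higher ranked one, the 3 highest and the 1 lowest members of each list, and 16 genes always named (Nkx2-5, Gata4, Tbx5, Tbx20, Hand2, Myh6, Myh7, Nppa, Actc1, Tnnt2, Myl2, Wt1, Tek, Alb, Foxg1 and Myod1). Of the peaks, the 5 with the highest signal and the 5 widest were named. Genes beyond this rule were chosen after their values were seen.

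The list named replicated was the main peak set. The plan made this depend on support in both replicates, which 72.8% of its peaks had, so an alternative kept only those peaks. Alternatives fixed beforehand were overlaps of 1 bp or of 50% of both peaks, equal numbers of top peaks, merging of touching peaks, a −log10 q of at least 2, −log10 p in place of signal, the pooled list, and each replicate's list alone. They also included a promoter of 2.5 kb, bases in place of midpoints, a CpG cut of 0.75, windows of 20 and 200 kb, numbers of peaks, unmatched random lists, matches outside soft-masked repeats, regions 20 kb away, valleys up to 500 bp, 2 other joining distances and the top 5% of domains. Added after seeing the data were a −log10 q of at least 5, the peaks with support in both replicates, list members on autosomes, matching on GC and CpG, and for valleys matches outside repeats and GC-matched regions. The tests of explanations in the closing section came after the patterns had been seen. The position of matches within valleys was first counted for all 18 motifs and then kept for CTCF, MEF2, GATA and the TAAT core to save run time.

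The analysis ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and cover functions were tested on 200 simulated interval sets and the motif search on planted matches, with 0 differences from direct counting. For gene list cover, on 21728 genes, 4.75% of random lists of 16 genes had p under 0.05. Adding 2 percentage points to 16 genes gave p under 0.05 in 12% of lists, adding 5 in 69.8% and adding 10 in 100%, so differences near 2 points would mostly be missed. These shares count p before adjustment. Under the adjusted threshold that called lists, they can only be the same or lower.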

Results

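H3K4me1 was profiled in mouse heart at embryonic day 14.5, in 1 group of 2 biological replicates with no other tissue or stage. The list of replicate 1 held 231126 peaks covering 108 Mb, and that of replicate 2 held 150701 peaks covering 63.2 Mb. The mean was 190914 ± 56869 peaks (SD, n = 2), and the covered share of the genome was 3.24% ± 1.21 (SD, n = 2). The list called on both replicates held 206386 peaks over 130 Mb. The list named replicated held 126010 peaks with a median width of 633 bp over 107 Mb, or 4.04% of the genome. Sequencing depth is unknown, since the files hold peaks only. With 1 group, the comparisons were between replicates, between classes of genes and between regions of the genome.

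The first question was how far the replicates found the same marked regions. Of the peaks of replicate 1, 42.8% were shared with replicate 2 (95% exact interval 42.6 to 43.0). Of the peaks of replicate 2, 75.6% were shared with replicate 1 (interval 75.3 to 75.8). Random placements gave 3.78% ± 0.0406 and 5.63% ± 0.0596 (SD over 100 placements), so sharing was 11.3 and 13.4 times as frequent. The placements kept only the chromosome and the peak lengths. These ratios therefore do not separate sharing of the same regions from a common preference for some parts of a chromosome. Of the strongest 10% of each list, 93.1% of peaks were shared in replicate 1 and 98.3% in replicate 2, and of the weakest 10%, 15.2% and 60.1%. The covered bases had a Jaccard index of 39.6%. Across 102073 matched peaks, which are not independent replicates, the authors' signal values had Spearman's rho of 0.356 and Pearson's r of 0.434. Across 21728 genes, which are not independent either, the covered percent of the 100 kb around the start site had rho = 0.978 between replicates. The shared percent of replicate 1 was 24.2% and that of replicate 2 37.1% when 50% of both peaks had to overlap.

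**Figure D1:**
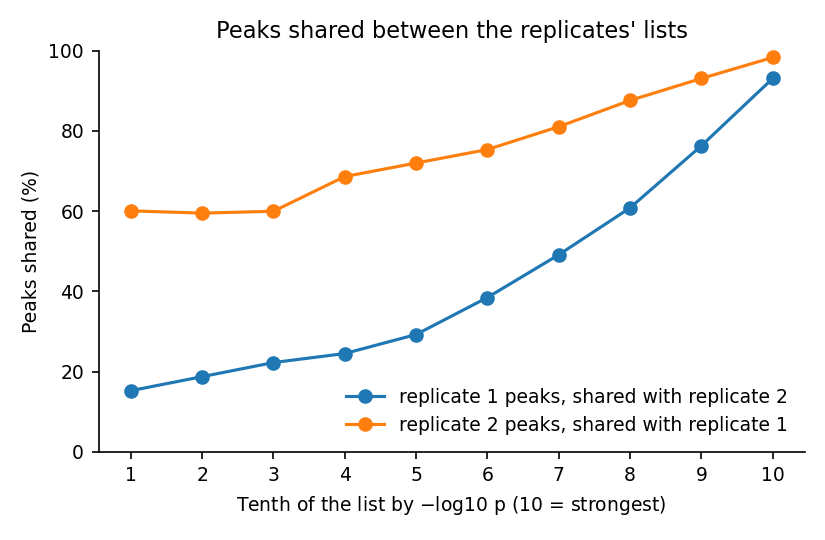
Percent of peaks of each replicate's list shared with the other replicate (y axis) in 10 equal parts of the list, ranked by −log10 p (x axis, 10 the strongest). Sharing goes from 15.2% to 93.1% for replicate 1 and from 60.1% to 98.3% for replicate 2.

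Every peak of the replicated list was identical to a pooled peak, and the list held 61.1% of the pooled peaks. Of its peaks, 91676 (72.8%) overlapped a peak in both replicates' lists. A further 28942 overlapped replicate 1 alone, 3900 replicate 2 alone and 1492 neither. All 91676 pooled peaks with support in both replicates were in the list. When 50% of both peaks had to overlap, 30.4% of the list had support in both.

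The mark lay mostly in introns and away from start sites. Introns held 58.8% of replicated peak midpoints, 1.38 times the share of random placements, and intergenic sequence held 23.5%, or 0.470 times. Promoters within 1 kb of a start site held 13.6%, or 3.03 times. Coding exons and 5' UTRs held 1.79% (1.43 times), 3' UTRs 1.45% (1.16 times) and noncoding exons 0.875% (1.44 times). In the replicates' own lists promoters held 12.2% ± 1.05, introns 60.2% ± 0.79 and intergenic sequence 23.2% ± 1.98 (SD, n = 2). All 6 classes lay beyond every one of 100 random placements, for which the smallest one-sided empirical p is 0.0099. The median distance to the nearest start site was 10.2 kb, and 75% of peaks were over 2.5 kb away. With promoters taken to 2.5 kb from a start site they held 25%, or 2.40 times the random share, and noncoding exons 0.441%.

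Around start sites, CpG-rich promoters, the class that holds most broadly expressed genes, had a dip in the mark with a peak on each side. In the replicated list 6.59% of 10170 CpG-rich start sites were covered at the start site itself, 31.7% at 700 bp upstream and 52.4% at 1100 bp downstream. The higher flank was 7.95 times the start site, and 8.52 ± 0.502 times in the replicates' lists (SD, n = 2). At 10637 CpG-poor start sites, 13.0% were covered at the start site, 15% at 300 bp upstream and 15.8% at 600 bp downstream. That ratio was 1.21, and 1.24 ± 0.0175 in the replicates' lists (SD, n = 2), so the classes differed by more than the spread between replicates. A peak lay within 5 kb of 93.6% of CpG-rich and 44.4% of CpG-poor start sites. With the CpG cut at 0.75 the ratios were 12.9 and 2.06.

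**Figure D2:**
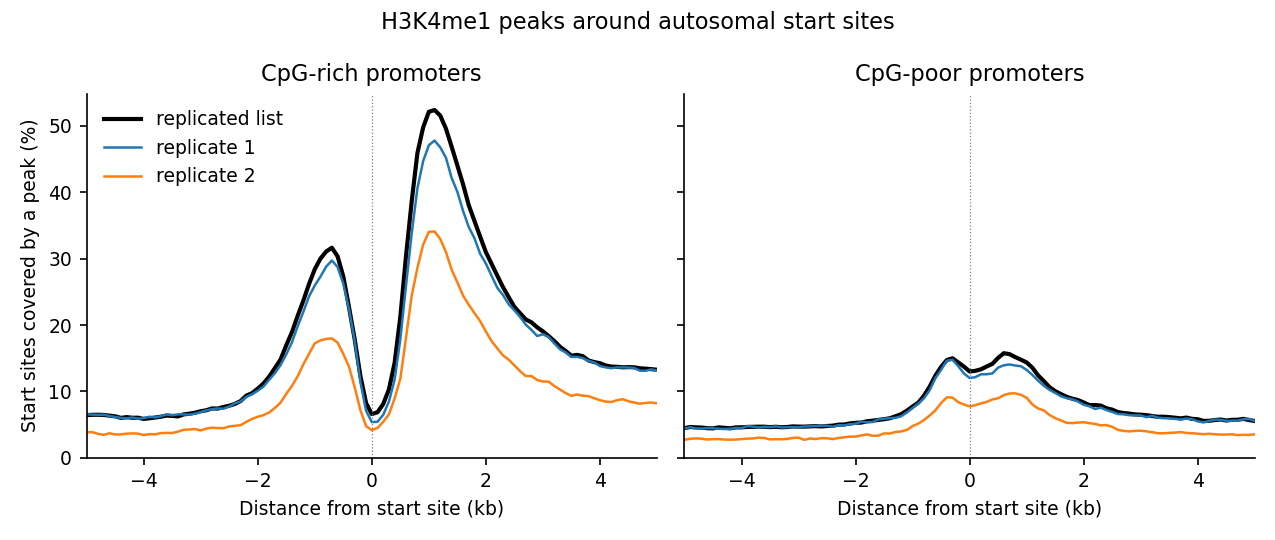
Percent of start sites covered by a peak (y axis) against the distance from the start site in kb (x axis), for CpG-rich and CpG-poor autosomal protein coding genes; lines stand for the replicated list and each replicate's list. CpG-rich start sites go from 6.59% at the start to 52.4% at 1100 bp downstream in the replicated list.

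The next question was which genes carried the most H3K4me1. The gene with the highest cover was Lrrfip1 (chromosome 1, 90998737 to 91128944, plus strand), where peaks covered 71.4% of the 100 kb around the start site. It was followed by Igf2r, the receptor that clears insulin-like growth factor 2 (chromosome 17, 12682406 to 12769664), at 61.9%, and Gse1 (chromosome 8, 120228456 to 120581390) at 61.7%. The collagen gene Col4a1, a basement membrane component, had 58.0%, Zmiz1 57.4%, Mical2 57.2% and Dab2ip 56.9%. Mical3, Ahdc1, Ski, Smad6, Pakap, Ncor2, Synpo, Zfpm1, Sorbs1, Sh3pxd2a, Rcsd1, Tead1 and Iqsec1 completed the 20 named, down to 48.5% at Iqsec1. The start sites used for Lrrfip1, Gse1, Dab2ip, Mical3, Pakap, Synpo, Sorbs1 and Iqsec1 lie inside their genes, away from the upstream end. Windows of these genes therefore hold mainly gene body. Zfpm1 encodes a cofactor of GATA factors, Smad6 an inhibitor of BMP signalling and Ncor2 a corepressor. In the replicates' own lists Lrrfip1 had 58.3% ± 8.60, Igf2r 53.0% ± 6.99 and Tead1 40.3% ± 9.59 (SD, n = 2). The median protein coding gene had 4.68%, the highest 10% began at 17.5%, and 19.1% of genes had no peak.

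Genes of heart muscle carried more H3K4me1 than genes matched on the number of start sites and the GC content of the window. The median of 22 cardiac transcription factors was 21% of the window, against 5.98% for random lists, and 13 members lay in the highest 10% of all genes. The median of 26 contractile genes was 19.9% against 8.86%, and that of 16 calcium handling and conduction genes 17.2% against 4.69%. For each of these 3 lists no random list reached the median (permutation test, p = 0.0002, the smallest that 10000 lists can give, adjusted p = 0.001). In the replicates' lists the medians were 16% ± 4.03, 15.3% ± 3.98 and 12.9% ± 5.79 (SD, n = 2). All 3 lists passed the test in each replicate's list alone, although the replicates differed in level.

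Among the transcription factors, Tead1 had 48.6%, Gata4 (chromosome 14, 63198922 to 63271692, minus strand) 44.3% and Myocd, a coactivator of serum response factor, 36.1%. The start site used for Gata4 lies inside the gene. Nkx2-5 had 24.9%, Hand2 21.3%, Tbx5 20.6% and Tbx20 17.0%. Isl1, a factor of early heart progenitors, was the lowest at 1.79%. Of the contractile genes, Tnni1 had 43.8%, Tcap 41.7% and Tnnt2, cardiac troponin T, 39.5%; the windows of Tnni1 and Tnnt2 overlap, as do those of Myh6 at 20.9% and Myh7 at 16.5%. Myl2 had 16.1%, Nppa, the atrial natriuretic peptide gene, 11.1%, Actc1 7.52% and Nebl 2.83%. In the lists of replicates 1 and 2, Myl2 had 18.2% and 10.7%, and Nppa 11.2% and 6.75%. Actc1 had 6.88% and 1.92% in these lists, and Nebl 2.32% and 0.681%. Jph2, which holds the junctions between surface membrane and calcium store, had 40%, the potassium channel gene Kcnh2 37.5% and the calcium release channel gene Ryr2 37.4%. The pacemaker channel gene Hcn1 had 1.32%.

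The other 12 lists did not pass the test after adjustment, which does not show that they equal matched genes. Cardiac signalling genes had a median of 10.1% (random lists 6.22%, adjusted permutation p = 0.169), with Smad6 at 50.8%, Smad7 at 45.2%, Erbb2 at 37.2% and Nrg1 at 1.05%. The window of Erbb2 overlaps that of the contractile gene Tcap. The start site used for Nrg1 lies inside the gene, far from its upstream end. Endothelial and endocardial genes had 10.4% (7.39%, adjusted permutation p = 0.264), with Eng at 37.2%, Notch1 at 29.4%, Egfl7 at 19.4%, Tek at 9.83% and Erg at 0.737%. The windows of Notch1 and Egfl7 overlap, and the start site used for Erg lies inside the gene, away from its upstream end. Smooth muscle and pericyte genes had 9.06% (7.44%, adjusted permutation p = 0.639), from Myl9 at 24.6%, Smtn at 20.3% and Pdgfrb at 13.2% down to Rgs5 at 0.606%. Housekeeping genes had 11.2% (7.78%, adjusted permutation p = 0.215), from Rplp0 at 29.7%, Ywhaz at 24.9% and Hsp90ab1 at 24.3% down to the X-linked Pgk1 at 0.884%. Epicardial genes had 3.76% (4.71%, adjusted permutation p = 0.647), with Upk3b at 11.2%, Msln at 10.7%, Wt1 at 7.71% and Gpm6a at 0.521%. Cushion and fibroblast genes had 4.29% (2.62%, adjusted permutation p = 0.387), with Snai1 at 24.8%, Fbln1 at 14.6%, Col1a1 at 13.5% and no peak in the window of Col3a1.

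The lists of other tissues and blood cells lay on both sides of their random lists. Liver genes had 1.76% (random lists 4.78%, permutation p = 0.0226, adjusted p = 0.0847), with Hnf1a at 11.1%, Ttr at 10.8%, Apoa1 at 10.7% and no peak around Alb or Serpina1a. Skeletal muscle genes had 3.90% (7.63%, adjusted permutation p = 0.135). Its fast troponin gene Tnnt3 had 45.7%, Myog 18.4%, Mylpf 14.3%, Myod1 1.40% and Myh8 none. Endoderm genes had 3.64% (6.56%, adjusted permutation p = 0.135), with Sftpb at 22.0%, Cdx1 at 13.8%, Sftpc at 10.8% and no peak around Ins2, whose start site here is that of its longest principal transcript, far upstream of the others. Neural genes had 4.73% (3.87%, adjusted permutation p = 0.647), with Snap25 at 10.7%, Pax6 at 7.37%, Lhx2 at 6.87%, Foxg1 at 2.97% and no peak around Slc17a6. Erythroid genes had 2.90% (4.73%, adjusted permutation p = 0.387), with Nfe2 at 23.5%, Slc4a1 at 11.1%, Hemgn at 9.59% and no peak around Rhag; without its 2 X-linked members, an alternative added after seeing the data, the median was 5.49% against 5.20%. Immune genes had 6.54% (6.83%, adjusted permutation p = 0.875), with Spi1 at 20.2%, Cd68 at 15%, then Laptm5, and no peak around Adgre1. The window of Spi1 overlaps that of the contractile gene Mybpc3, and the window of Cdx1 overlaps that of the pericyte gene Pdgfrb. Their values are therefore not separate evidence for the lists they stand in. In the 20 kb around the start site, cardiac signalling, endothelial and housekeeping genes were called higher, and liver and erythroid genes lower (adjusted permutation p from 0.0105 to 0.0472). The erythroid call (adjusted permutation p = 0.0472) was not repeated without the 2 X-linked members, so it may rest on them. From replicate 1's list alone, liver (adjusted permutation p = 0.0450) and endoderm genes (adjusted permutation p = 0.0285) were called lower. Both lists hold members whose windows overlap, 4 pairs in liver and 1 in endoderm, so these p can be too small.

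**Figure D3:**
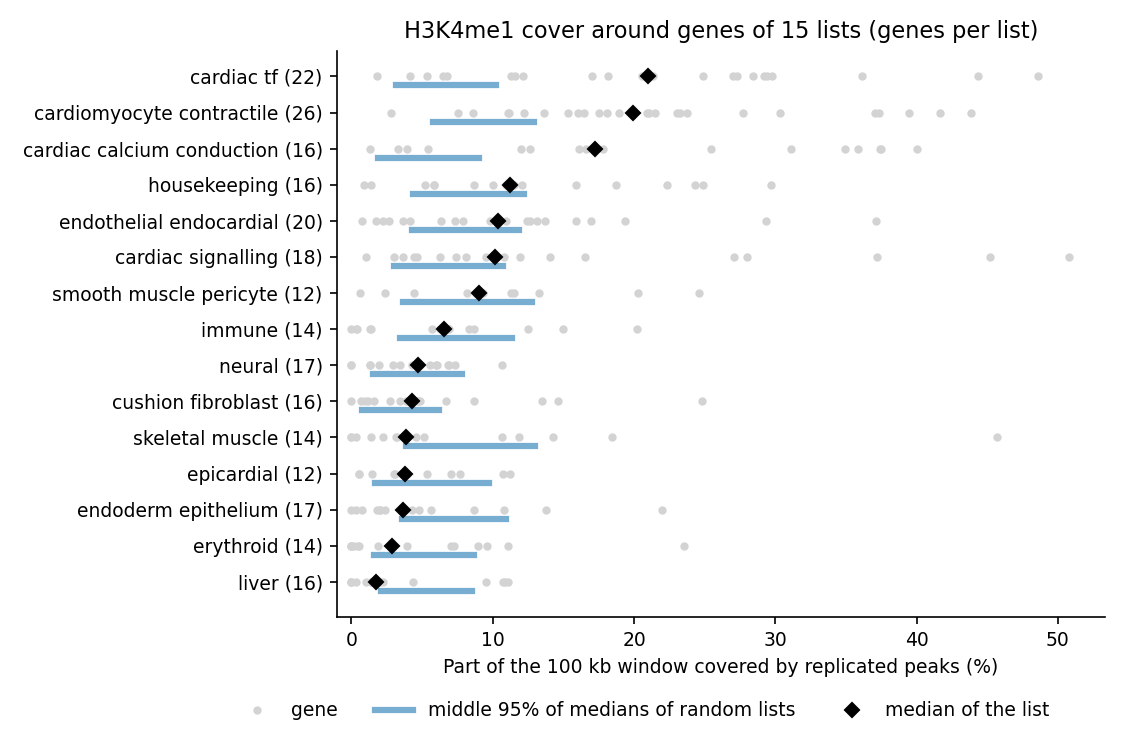
Percent of the 100 kb around the start site covered by replicated peaks (x axis) for genes of 15 lists (y axis, number of genes in brackets). Grey points are genes, black diamonds list medians and blue bars the middle 95% of medians of random matched lists; 3 cardiac lists, with medians of 21%, 19.9% and 17.2%, lie above their bars.

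Joining neighbouring peaks gave 60287 domains, and the top 603 by covered length held 11.9% of all covered bases. The most covered domain lay at Mical2 (chromosome 7, 112202369 to 112320382) with 88.2 kb under 51 peaks, followed by domains nearest to Msi2 (77.8 kb), Shb (77.8 kb), Nfib (74.1 kb) and Gse1 (71.4 kb). Of 22 cardiac transcription factors 9 were nearest to a top domain, Meis1, Prdm16, Tead1, Gata4 and Myocd among them (odds ratio 20.1, Fisher's exact test, adjusted p = 2.78e-07). Of 16 calcium handling and conduction genes 6 were, Jph2, Ryr2 and Kcnh2 among them (odds ratio 17.3, Fisher's exact test, adjusted p = 6.63e-05). Of 26 contractile genes 4 were (odds ratio 5.21, Fisher's exact test, adjusted p = 0.0540), Tcap and Actn2 among them. Cardiac signalling and housekeeping had 2 members each, endothelium and smooth muscle 1 each, and the other 8 lists 0, none of them past the threshold. The test did not adjust for the length of genes or of their surroundings. Contractile genes passed it in other settings, both replicates' lists alone among them (odds ratios 11.6 and 7.29), and calcium handling genes did not when peaks further apart were joined (odds ratio 6.41).

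Single peaks of the highest signal lay inside genes. The first was in an intron of Bcar1, which encodes an adaptor of cell adhesion (chromosome 8, 111732278 to 111737449, signal 11.6). Others lay in an intron of the deacetylase gene Hdac5 (chromosome 11, 102206320 to 102210615, signal 11.5), in the noncoding RNA gene Gm36660, 49.4 kb from the start of Zfp36l1 (chromosome 12, 80062192 to 80065083, signal 11.5), and in an intron of Ncor2 (chromosome 5, 125150461 to 125153275, signal 11.2). The next lay in Ptp4a3 and covered an annotated start site (chromosome 15, 73725119 to 73734674, signal 11). The widest were in Iqsec1 (chromosome 6, 90696781 to 90714333, 17553 bp), Tns1 (chromosome 1, 74019921 to 74036990, 17070 bp), Dab2ip (16237 bp), the muscle chaperone gene Bag3 (chromosome 7, 128527733 to 128543938, 16206 bp) and Abtb2 (16058 bp).

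Matches to MEF2 and TEAD motifs had the largest ratios among the motifs with over 1000 matches in distal peaks. In 92599 distal peaks MEF2 matches occurred 0.185 times per kb against 0.115 in GC-matched regions, a mean log2 ratio of 0.70 ± 0.10 (SD over 19 autosomes). TEAD matches had 0.67 ± 0.09, MEIS 0.33 ± 0.07, NKX2 0.33 ± 0.04, AP1 0.33 ± 0.10 and GATA 0.19 ± 0.03. All 6 were higher on 19 of 19 autosomes (exact sign test, adjusted p = 1.14e-05). Smaller ratios passed the test for the TAAT homeobox core (0.10 ± 0.07), the CArG box bound by serum response factor (0.09 ± 0.11) and the T-box site (0.09 ± 0.09), and for the rarer CRE (0.25 ± 0.29), ETS (0.45 ± 0.49) and RFX (0.81 ± 0.93) sites. The call of RFX rests on a change of the test made after its first output was seen (adjusted p = 0.00627 by the exact sign test, and 0.252 in the first version). CTCF matches were fewer (log2 ratio −0.44 ± 0.37, lower on 17 of 17 autosomes without a tie, adjusted p = 3.92e-05 by the exact sign test), as were REST matches (17 against 55 in all). The E-box of HAND and TWIST factors (−0.03 ± 0.03), SOX (−0.02 ± 0.06), HNF4 (0.16 ± 0.24) and HNF1 sites did not pass the test. Peaks had fewer bases in soft-masked repeats (13.7%) than the GC-matched regions (31.2%). Against regions 20 kb away, whose GC content was 44.2% against 47.6% in the peaks, the ratio of MEF2 was 0.01 and that of GATA −0.02, and neither was called, the TAAT core was called lower (−0.47) and CTCF was not called, while TEAD had 0.75. The calls of CArG, T-box, CRE, ETS, RFX and REST sites were each lost in at least 2 alternatives, and outside repeats the T-box was called lower; those of TEAD, MEIS, NKX2 and AP1 held in all.

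In the valleys between neighbouring distal peaks, MEF2 and CTCF matches were denser than in the peaks beside them. Across 19329 valleys the mean log2 ratio was 0.88 ± 0.11 for MEF2 and 0.77 ± 0.16 for the TAAT core, both on 19 of 19 autosomes (exact sign test, adjusted p = 2.29e-05), and 0.10 ± 0.11 for GATA (16 of 19 autosomes). CTCF matches, at 0.0161 per kb against 0.00524, had 1.65 ± 0.99 and were denser on 18 of 19 autosomes, from 138 matches in the valleys. TEAD (−0.45 ± 0.26), MEIS (−0.32 ± 0.17), AP1 (−0.29 ± 0.22), the E-box (−0.26 ± 0.08), the T-box (−0.23 ± 0.21) and SOX (−0.18 ± 0.15) were less dense. Valleys had a GC content of 43.4% against 47.8% in the flanking peaks, and 27.2% against 14.4% of their bases lay in soft-masked repeats. Outside these repeats, a setting chosen after seeing the data, 2 motifs lost their call in valleys. Against GC-matched regions outside peaks, chosen after seeing the data, MEF2 (0.53) and CTCF (1.66) were still called higher, while TEAD, AP1, MEIS, the T-box and the TAAT core were no longer called and GATA was lower (−0.14).

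**Figure D4:**
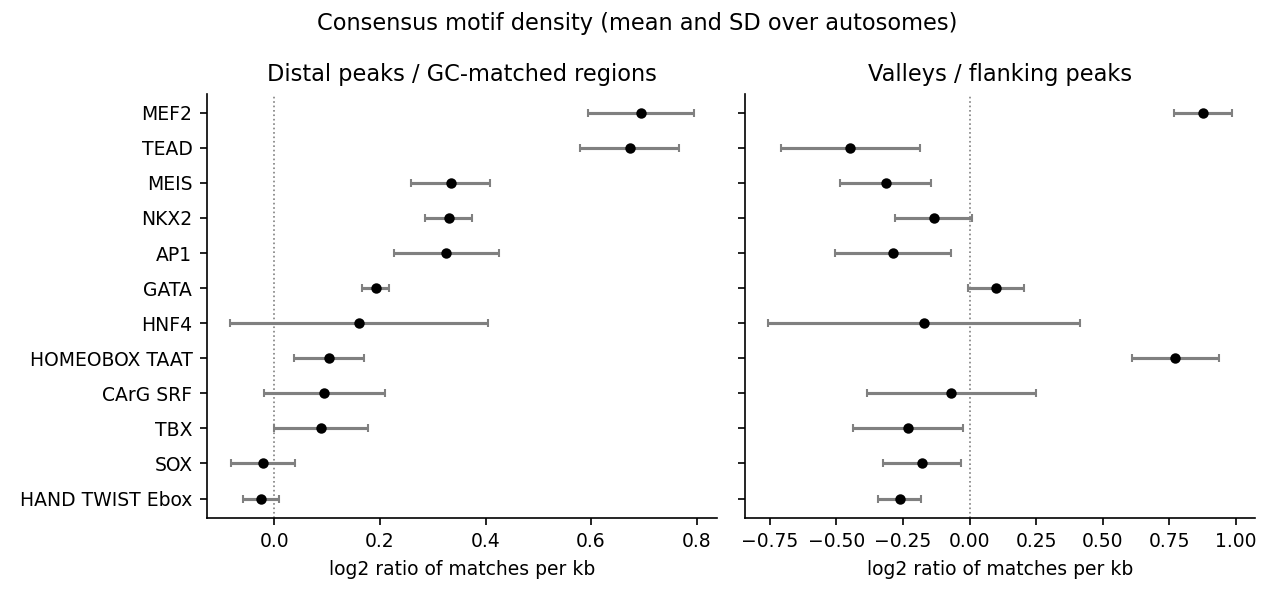
Mean log2 ratio of motif matches per kb with SD over autosomes (x axis) for motifs with over 1000 matches in distal peaks (y axis), in distal peaks against GC-matched regions (left) and in valleys against flanking peaks (right). MEF2 is at 0.70 and 0.88, and TEAD at 0.67 and −0.45; the panels have different scales.

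The X chromosome held few peaks. It had 896 replicated peaks, or 5.48 per Mb, against a mean of 52.9 ± 8.31 per Mb (SD over 19 autosomes) and a range from 40.5 on chromosome 14 to 75 on chromosome 11. The ratio was 0.104, and it was 0.150 in replicate 1, 0.0882 in replicate 2 and 0.155 in the pooled list. X held 6.18% of the genome and 0.711% of the peaks. The median cover of its 948 protein coding genes was 0, against 5.09% on autosomes. Start sites of protein coding genes with a peak within 5 kb were 16.7% on X (95% Wilson interval 14.4 to 19.2) and 68.5% on autosomes. The median −log10 p of X peaks was 6.49 against 8.23 on autosomes, and among peaks with −log10 q of at least 5, chosen after seeing the data, the ratio was 0.0558. No list had a peak on Y.

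**Figure D5:**
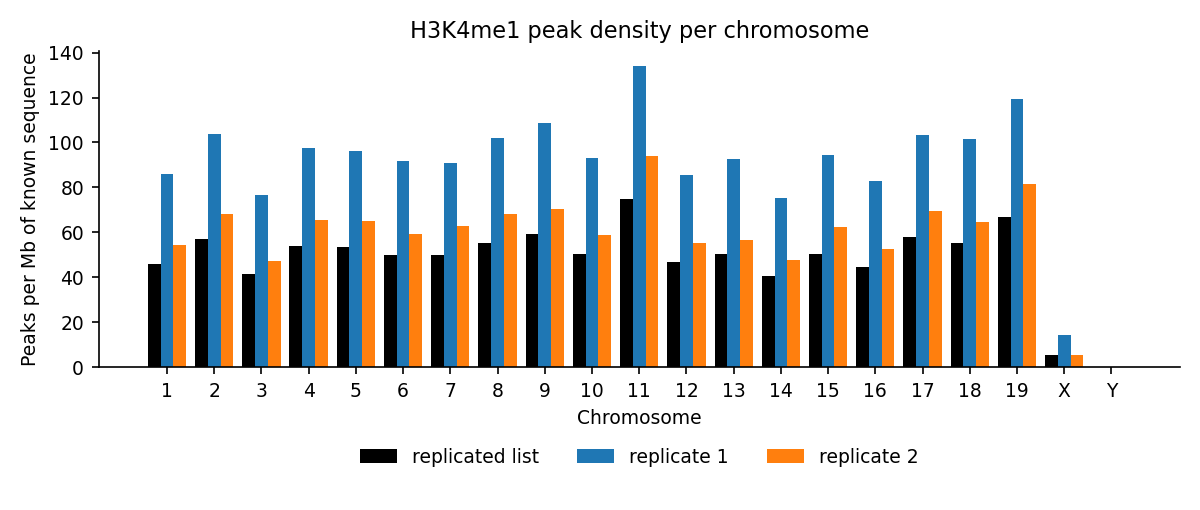
Peaks per Mb of known sequence (y axis) on each chromosome (x axis) in the replicated list and each replicate's list (bars). In the replicated list X has 5.48 per Mb, below the autosomal range of 40.5 to 75, and Y has none.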

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

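The settings with a −log10 q of at least 5, support in both replicates, GC and CpG matching, list members on autosomes and the 2 added valley comparisons were chosen only after the data were seen. Of 110 values that answer a comparison under an alternative, 74 kept direction and call or stayed close to the first value (within the spread between replicates or the interval, or within 1.5 times for counts), and 36 moved. Of those for single lists, features or motifs, 492 kept their side of the threshold, among them uncalled ones that changed sign, 33 lost the call and 20 gained one. A further 12 changed sign with a call in at least 1 of the 2 settings. Of these, 5 were of valleys set beside GC-matched regions outside peaks, which is a different reference from the flanking peaks. The 3 cardiac gene lists stayed higher in window cover under all alternatives of that test, but not in the test of broad domains. Promoters stayed over and intergenic sequence under their reference share, from 2.40 to 3.19 times and from 0.402 to 0.499 times. The 2.40 is for promoters of 2.5 kb. The 0.402 is for bases in place of midpoints, which were set beside the bases of the genome without random placements, so only the direction was judged. The lists had no touching peaks, so merging left them as they were, and its values among the 74 could not move. A −log10 q of at least 2 kept 98.3% of the replicated list, so that setting was a weak alternative for that list.

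Counting any shared base gave 49.3% and 84.2% shared peaks for replicates 1 and 2 and 73.3% of the replicated list with support in both. Asking 50% of both peaks gave 24.2%, 37.1% and 30.4%. Equal numbers of top peaks gave 54.3% and 63.3%. With −log10 q of at least 5 the shares were 39.8% and 72.1%, rho between signals 0.241, the X ratio 0.0558 and the flank ratios 9.64 and 1.34. With −log10 q of at least 2 rho was 0.337 and 1 motif was lower in distal peaks; from −log10 p, rho was 0.425. The pooled list gave an X ratio of 0.155 and flank ratios of 7.26 and 1.17. Support in both replicates gave a CpG-poor flank ratio of 1.26 and 1 lower motif. A CpG cut of 0.75, which moves genes between classes, gave 12.9 and 2.06. From 1 replicate's list alone, the X ratio ran from 0.0882 to 0.150, the flank ratios from 8.16 to 8.87 and from 1.23 to 1.25, and lists called lower from 0 to 2.

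A window of 20 kb called 6 lists higher and 2 lower, and 200 kb called 1 lower, endoderm. Joining peaks further apart left 1 list over-represented near top domains, cardiac transcription factors. In distal peaks, matches outside repeats gave 4 lower motifs, with the T-box at −0.0704, and GC and CpG matching gave 1. Against regions 20 kb away, with a lower GC content, GATA was at −0.0172, the TAAT core −0.468, HNF1 −0.908, the E-box 0.0517 and SOX 0.0619. From 1 replicate's list alone SOX ran from 0.00266 to 0.0341. Valleys against GC-matched regions outside peaks, in place of the flanking peaks, had 2 higher and 3 lower motifs, with GATA at −0.14, TEAD 0.12, the T-box 0.10, AP1 0.126 and MEIS 0.0842. The causes of these changes were not tested. The change of the sign test, made after its output was seen, gave RFX its call. Depth could not be assessed from peaks.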

Other observations

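The tests of GC content and repeats for the CTCF matches, of the filtering step for X, and of the overlap rule were chosen only after the result was seen, and so were the genes named in this part. The X-linked gene with the most H3K4me1 was Bcor, a corepressor of BCL6, with 26.1% of its window covered under 31 peaks, the only X-linked gene in the highest 10% of all genes. Stard8 had 16.5%, Tsc22d3, a glucocorticoid-induced gene, 11.9%, Tbl1x 11.3% and Elf4 9.97%. The densest 5 Mb of X (10000001 to 15000000) held 25.8 peaks per Mb, against a median of 47.8 in 465 autosomal stretches of that length, and 19 of 33 X stretches lay below the lowest 5% of the autosomal ones. The cover of Hox genes, which pattern the body axis, was taken in the 10 kb around the start site. In the Hoxa cluster (chromosome 6) Hoxa6 had 27.1%, Hoxa5 19.3%, Hoxa3 16.4% and Hoxa2 5.56%, while Hoxa9 and Hoxa10 had none, Hoxa11 5.66% and Hoxa13 12.4%. Windows of neighbouring Hox genes can overlap. The start site used for Hoxa3 lies between those of Hoxa6 and Hoxa7, and that of Hoxd3 between those of Hoxd8 and Hoxd4. The medians of paralogues 1 to 5 and 9 to 13 were 15.6% and 2.83% in the Hoxa cluster. In the other 3 clusters the medians were closer and the second was the higher, with 7.44% and 8.67% in Hoxb, 4.03% and 4.41% in Hoxc, and 7.92% and 9.12% in Hoxd. The second value of Hoxb and the first of Hoxc rest on 2 genes each. Over all clusters the medians were 7.87% (15 genes) and 6.365% (16 genes). None of these differences was tested.

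Few peaks lay on X. The step from pooled to replicated peaks is argued against as the whole source, since the ratio of X to autosomes was at most 0.155 in the pooled list and the replicates' lists. The ratio was 0.155 in the pooled list and 0.104 in the replicated list, so the step may account for a part. Sequence composition may account for part: autosomal 100 kb windows matched on start sites, GC content and repeats held 18.1 peaks per Mb against 5.84 on X, a ratio of 0.322. The same comparison gave 0.833 to 1.2 for the 19 autosomes, so composition as measured did not account for the whole, although 0.322 passes the bound of 0.33 by less than the SD over autosomes (0.0819); matching on coding genes, added afterwards, gave 0.303. Fewer X copies in a pool with males could lose weak peaks at the threshold, but −log10 p of autosomal peaks had to be scaled by 0.177 to leave as few, while a factor of 0.5 left 81.2%; how −log10 p scales with copies is not known, so this stays open, as does the control used. No biological explanation was tested.

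Of the replicated peaks, 34334 lacked support in at least 1 replicate's list. Too strict an overlap rule is argued against, since counting any shared base raised the supported share only to 73.3%. Selection by strength may have played a part: among pooled peaks without support in both, −log10 p told those in the list (median 5.87) from those left out (median 4.16) with an area under the curve of 0.809, between the bounds of 0.6 and 0.9 set before this value was seen. A plain threshold on this −log10 p would separate them fully, so it was not the only rule for these peaks. Whether strength measured in another way decided stays open, because the steps between the lists are not given in the sources used here. No biological explanation was tested.

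CTCF matches were denser in valleys than in the peaks beside them. Lower GC content is argued against as the whole cause, since the mean log2 ratio was 1.66 against GC-matched regions, and repeats likewise, with 1.85 outside soft-masked repeats. A factor bound near the middle of the valley was a candidate explanation, but 25.4% of 138 CTCF matches lay in the central part of equal length to each outer part (exact 95% interval 18.3 to 33.5), and the interval reaches just past an even spread, which leaves it open. The share was 32.8% for MEF2 (31.0 to 34.6), 32.7% for GATA and 31.4% for the TAAT core (29.8 to 33.0), so none of the 4 lay above an even spread. No biological explanation was tested.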
